A study of Mus musculus with 20 samples.

How the data were processed

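RNA was profiled in populations sorted from the spleen of C57BL/6 mice on postnatal day 21. Per the labels' protocols, the sort was done on a BD Influx at a purity of 95 to 99%, total RNA was purified with an RNeasy mini kit, and libraries were made with an Illumina TruSeq kit. The 20 libraries fall into 5 groups of 4: B cells and cDC1 of WT mice, and B cells, cDC1 and CD11cint cells of mice labelled March1-/-. Groups and replicate numbers were taken from the titles given to the libraries. How many mice a library holds is not given in the sources used here.

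The authors deposited read counts per gene as whole numbers, in 40 tables, 1 for each library and each of 2 sequencing lanes, and in a table of the whole series. The submitters' processing notes name CASAVA, FastQC, STAR, Subread, edgeR and limma and the build GRCm38 (mm10), with no versions. Whether counting used the strand is not given in the sources used here, so reads of a gene and of a gene on the opposite strand over the same bases cannot be told apart. Of the 137 genes named in the text, 33 share exon bases with another annotated gene, 30 of them with a gene on the opposite strand. More than 10% of the exon bases are shared for Cd9 (10.7%), Entpd4 (26.1%), Entpd4b (21.1%), Mid1 (14.2%), G530011O06Rik (40%), Gm15247 (27.3%), Gm15726 (28.3%) and Xist (11%). All of these shares are with a gene on the opposite strand.

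The counts of the 2 lanes were added. The sum was equal to the deposited table of the series in all 566760 cells of 28338 genes by 20 libraries. No entry without a gene name was present, and every column was matched to a library. Of the gene identifiers, 28290 matched the GENCODE M21 annotation of GRCm38, which gave symbols, types and coordinates, and the other 48 held 0.0414% of counts. The total per library was 22491084 to 32751804 counts. A count of 3 corresponds to 0.0916 to 0.1334 CPM, which was taken as the floor of detection. It covers counting error only, since the reads carry no molecular identifiers. The lanes of 1 library differed by no more than sampling noise (chi-square per gene 0.989 to 1.031 in 20 libraries), whereas 2 libraries of a group differed by 4.547 to 71.401 in 30 pairs, with the highest values in pairs that held library 1 of March1-/- cDC1 or of CD11cint cells, so each library was counted as a separate sample.

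Differences were tested with edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3) on the deposited counts, in 1 fit of all 5 groups, with filterByExpr by group, TMM factors and robust estimation. The filter kept 18710 genes with 99.9459% of counts. The fit had 15 residual degrees of freedom, a common dispersion of 0.0119 and a biological coefficient of variation of 10.91%. Genes with a Benjamini-Hochberg adjusted p under 0.05 are said to be called, to pass the test, or to have risen or fallen. There were 7 contrasts: March1-/- against WT in B cells and in cDC1, CD11cint against B cells and against cDC1 of March1-/- mice, cDC1 against B cells in each genotype, and the interaction of genotype and cell type. The tests, the lists, the naming rule and most alternatives were fixed before the data were examined.

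Fixed gene lists were tested with limma's camera (limma 3.58.1) at a preset correlation of 0.01 and with a correlation estimated per list, and with fry, adjusted over the lists of a contrast. The lists were pan B, marginal zone, follicular, B-1, germinal centre, plasma cell and CD11c+ T-bet+ B cells. Lists of cDC1, pan cDC, cDC2, plasmacytoid dendritic cells, spleen macrophages, monocytes, neutrophils, T cells, NK cells and erythroid cells were used as well. The remaining lists were MHC class I and class II presentation, costimulation, complement and its receptors, MARCH ubiquitin ligases, the Notch pathway, interferon response, unfolded protein response, proliferation and immediate early genes. A platelet list had fewer than 5 tested genes and was not tested. Elane, Klf1, Pf4, Gp9, C3ar1, C5ar1, March4 and Hey1 fell below the count filter, and Vsig4, March10 and March11 were not used here. Some genes stand on more than 1 list, such as Itgax, Cr2, Dtx1 and Itgam.

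The position of a library is the median over axis genes of its log2 CPM (prior count 2), scaled to 0 at the WT cDC1 mean and 1 at the WT B cell mean. Axis genes were called between WT cDC1 and WT B cells with an absolute log2 fold change of at least 2 and a mean of at least 10 CPM in the higher group. Specific genes were axis genes with at least 4 on the log2 scale, and those of highest specificity had at least 6. Positions and summed levels were compared with exact permutation tests in R. The counts were read and the libraries described in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3. Figures were drawn with matplotlib 3.10.9. Genes within 20 Mb of March1, measured between gene edges and leaving out March1, were compared with all others by Fisher's exact test, and intervals are at 95%.

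Named genes were chosen by a rule. It takes March1, Itgax, Cd24a, Cd8a, Xcr1, Cr2, C3, H2-Ab1 and Cd86 in every comparison. It adds the 10 called genes with the largest and the 10 with the smallest log2 fold change among those with a mean of at least 10 CPM in the higher group and all 4 libraries of a group above all 4 of the other. Immunoglobulin and T cell receptor segments and predicted genes were not named under this part. The rule further takes up to 4 members of each list described, by smallest adjusted p, and up to 10 genes for the interaction. A few results that the rule takes are not reported here. Outside the rule, and after their values were seen, Abca1, Cxcr5, Rgs13, H2-DMb2, H2-Ob, H2-K1, Klf2, Haus8, Jak3, Mid1-ps1, Gm21860, Gm47283, Gm21742 and Gm21748 were named, and in the closing part the immunoglobulin constant genes, Igkv2-107, the other genes of chromosome Y, Xist and 4 genes next to Mid1.

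The test across genes and the measure of cDC1 level were tested on simulated data, with 50 genes changed at each fold. For March1-/- against WT B cells (18495 genes) 22, 56, 74 and 94% of genes changed 1.25-, 1.5-, 2- and 4-fold were called, with 4 false calls among 127. For CD11cint against B cells (18503 genes) these shares were 4, 52, 76 and 92%, with 8 false calls among 120. Simulated cDC1 levels of 0, 0.5, 2 and 10% in CD11cint cells were recovered as −0.0544, 0.532, 1.99 and 10.3% over 438 or 439 genes. These recovered values are above the B cell background, which was subtracted, whereas the levels given in Results are not. The simulated libraries were drawn from mixtures of the mean March1-/- B cell and cDC1 profiles, a setting that favours recovery.

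The replicate numbers of the titles were checked for pairing through the correlation of deviations from the group means. March1-/- B cells and CD11cint cells with the same number deviated together (Pearson's r across genes 0.503, 0.213, 0.243 and 0.407), and all 8 libraries correlated best with the library of their own number. No source says what a shared number stands for. The other pairs of groups did not have every correlation above 0.1. The alternatives were DESeq2 1.42.0, limma-voom, RLE factors, no filter, the compared groups alone, each lane alone, leaving out immunoglobulin genes (347), a replicate block, and each library left out in turn. Other thresholds of the position, level and window were tried as well. Some alternatives were added after the data had been seen. They left out chromosome 8, the genes at least 16-fold higher in WT B cells than in WT cDC1, or all March1-/- libraries numbered 1. A window of all of chromosome 8 and splits that moved both cell types of a number together were added then too. So were sign flips within the 4 pairs of March1-/- B cell and CD11cint libraries for the position and level.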

Results

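RNA was sequenced from cell populations sorted from the spleen of C57BL/6 mice on postnatal day 21. The mice were wild type (WT) or labelled March1-/-. March1 encodes MARCH1, a membrane-bound ubiquitin ligase known to remove MHC class II and CD86 from the surface of antigen-presenting cells. B cells and type 1 conventional dendritic cells (cDC1, the dendritic cells specialised in cross-presentation) were sorted from both genotypes. Another population, with intermediate CD11c and CD8 and positive for CD24 (CD11cint cells), was profiled from March1-/- mice. WT CD11cint cells were not analysed here. The title of the series places the work in the transfer of membrane from dendritic cells to marginal zone B cells and the display of complement C3 with MHC class II. Each of the 5 groups held 4 libraries, and the total count per library in genes was 22491084 to 32751804. The labels do not say that the libraries of a group came from separate animals, so p-values measure only the spread between these libraries, which may be technical in part. Levels are given as CPM (normalised read counts, relative to TMM-scaled library sizes), as mean ± SD over n = 4 libraries. Log2 fold changes are given ± SE. The first principal component held 88.0% of the variance and placed all 8 cDC1 libraries apart from the 12 B cell and CD11cint libraries. The next component held 3.2%. Some March1-/- libraries numbered 1 stood apart from their groups. On the third component, which held 1.53%, B cell library 1 lay at 34.6 (−0.524 to 8.29 in the others) and CD11cint library 1 at 35.8 (−30.5 to −5.79). In chi-square per gene, CD11cint library 1 differed from the others of its group by 45.4 to 70.9, which differed among themselves by 7.06 to 12.2, and cDC1 library 1 by 55.6 to 71.4, against 12.3 to 21.3.

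March1 itself (ENSMUSG00000036469, chromosome 8, 65617900 to 66471637, plus strand, GRCm38) was counted in all 20 libraries. Its level was 137.4 to 158.6 CPM in the WT B cell libraries and 133.9 to 170.8 CPM in the March1-/- B cell libraries. It was 321.9 to 379.9 CPM in WT cDC1, 253.5 to 272 CPM in March1-/- cDC1 and 119.2 to 134.5 CPM in CD11cint cells. March1 did not pass the test between B cells of the 2 genotypes (log2 fold change 0.04 ± 0.07, edgeR adjusted p = 0.89). It fell in March1-/- cDC1 (−0.38 ± 0.07, edgeR adjusted p = 0.00306). The part of the gene removed in the mutant allele is not given in the sources used here, so a count over the whole gene checks nothing about the genotype. March1-/- below therefore means the libraries labelled March1-/-, in every direction that is drawn.

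Itgax, which encodes CD11c, was at 1092 ± 57.6 CPM in WT cDC1 and 1197 ± 67.5 CPM in March1-/- cDC1. It was at 10.7 ± 2.22 CPM in CD11cint cells, close to the 10.4 ± 2.47 CPM of March1-/- B cells (log2 fold change 0.04 ± 0.20, edgeR adjusted p = 0.929). Cd8a was at 944.4 ± 22 CPM in March1-/- cDC1, 5.54 ± 1.06 CPM in CD11cint cells and 1.83 ± 0.42 CPM in March1-/- B cells. Cd24a was lower in CD11cint cells than in March1-/- B cells, at 729.8 ± 64.6 against 905.3 ± 84.6 CPM (−0.31 ± 0.08, edgeR adjusted p = 0.0069). C3 was at 3.07 to 5.03 CPM on average in every group.

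**Figure D1:**
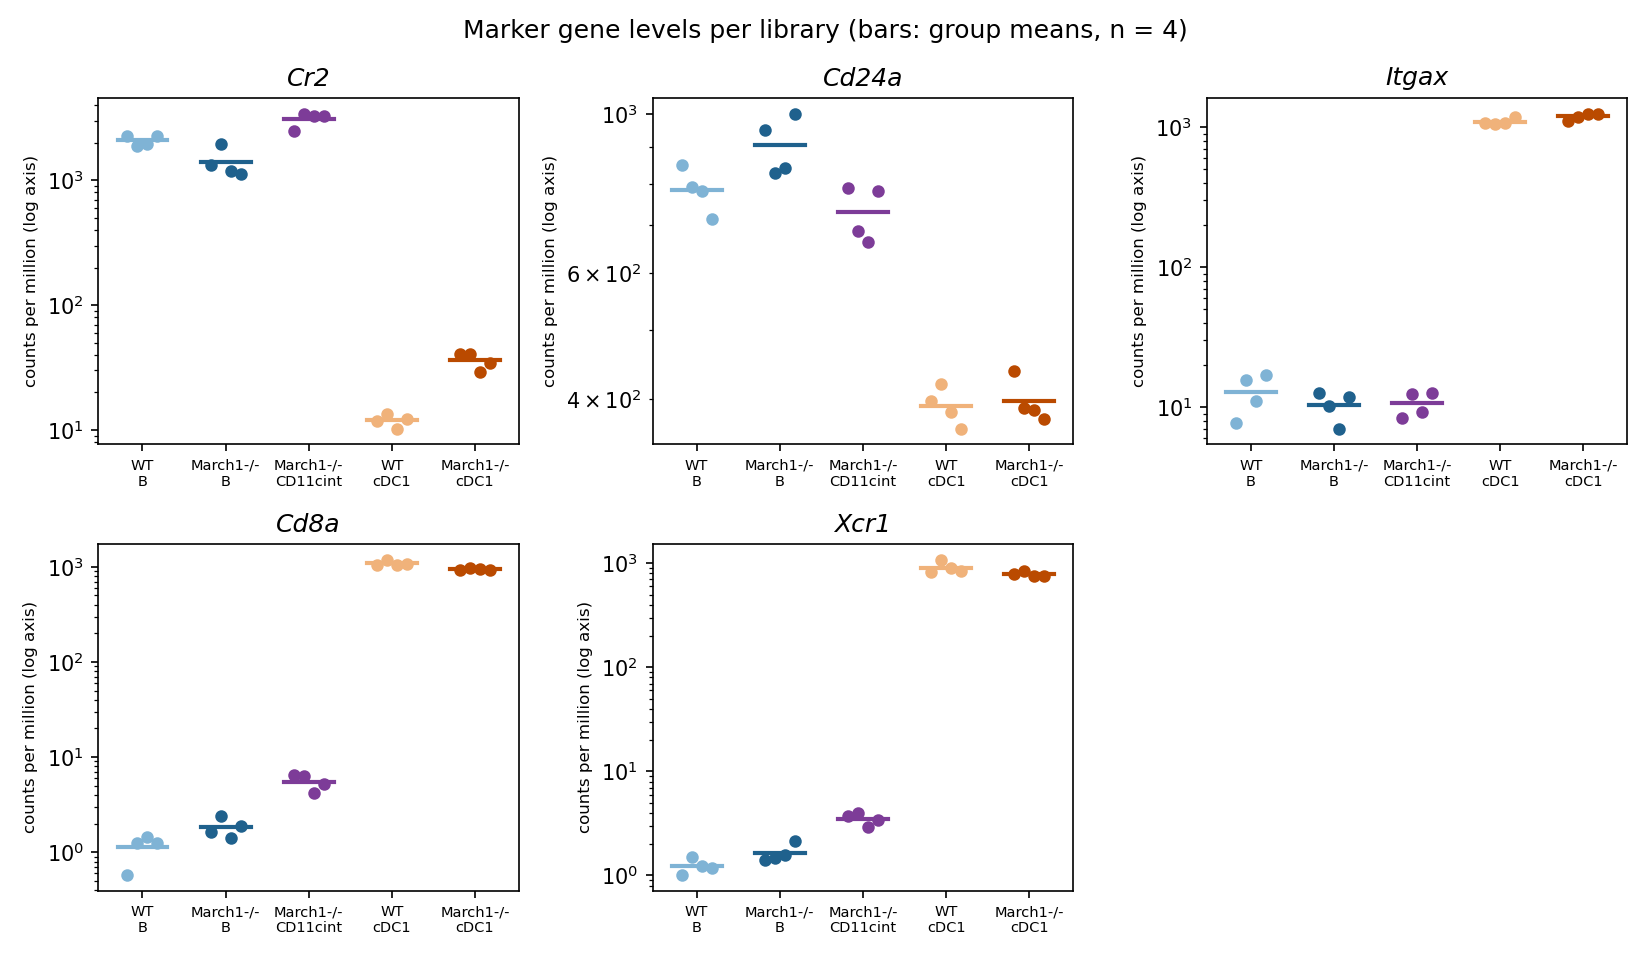
Level of 5 marker genes in each of the 20 libraries, in CPM on a log axis; points are libraries and bars are group means (n = 4). CD11cint cells lie with the B cells for Itgax, above the March1-/- B cells for Cr2, Cd8a and Xcr1, and far below the cDC1 libraries for Itgax, Cd8a and Xcr1.

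CD11cint cells were compared with B cells of the same genotype to see how the RNA of the sorted population differs from that of B cells. Marginal zone genes were higher in CD11cint cells. Marginal zone B cells lie at the edge of the white pulp and take up blood-borne antigen. Of the 18 genes of their list 17 rose and 1, Abca1, fell, with a median log2 fold change of 1.13. The counts were the same adjusted over the list alone (camera adjusted p = 1.47e-30, and 0.000879 with an estimated correlation). Cr2, which encodes complement receptor CD21, was at 3112 ± 418 CPM against 1399 ± 369 CPM (log2 fold change 1.15 ± 0.15, edgeR adjusted p = 3.73e-06). The sphingosine-1-phosphate receptor gene S1pr3 rose by 1.60 ± 0.12, Asb2 by 2.04 ± 0.15, Sema7a by 1.44 ± 0.11 and Cd9 by 1.19 ± 0.09 on the log2 scale (edgeR adjusted p at most 3.83e-09). Genes of follicular B cells moved the other way: 8 of 9 fell and 1 (Cxcr5) rose, a call lost in the fit of the compared groups alone (edgeR adjusted p = 0.0621) and without March1-/- B cell libraries 3 or 4 or CD11cint libraries 1 or 2 (0.108, 0.112, 0.104 and 0.103). The counts were the same adjusted over the list alone (camera adjusted p = 1.1e-14, and 0.000453 with an estimated correlation). Fcer2a, which encodes CD23, was at 166.9 ± 13.6 CPM against 458.8 ± 30.7 CPM, and Ighd, the heavy chain gene of IgD, at 601 ± 38.0 against 1387 ± 110 CPM. Of 18710 genes tested, 4613 were called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2335 higher and 2278 lower in CD11cint cells. Of these, 350 and 694 changed at least 2-fold. The count was 3018 in a fit of the compared groups alone.

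Beyond these lists, the largest rises over March1-/- B cells among the genes the naming rule allows included Ffar2, a receptor for short-chain fatty acids (log2 fold change 2.28 ± 0.17), the tetraspanin gene Tspan15 (2.26 ± 0.20), Tsga13 (2.20 ± 0.23), Trem1 (2.03 ± 0.17), AW011738 (1.90 ± 0.14), Adam28 (1.90 ± 0.24), Sorbs2 (1.90 ± 0.17) and Rundc3b (1.87 ± 0.21). Apol7c, which was at 818.7 ± 97.0 CPM in March1-/- cDC1, rose by 1.93 ± 0.23. The largest falls that the rule allows were in Nyx (−4.95 ± 0.34), Rgs13 (−4.03 ± 0.20), Wnt10a (−3.40 ± 0.21), Sdc1 (−3.27 ± 0.22), which encodes syndecan-1 (CD138), Ahnak (−3.18 ± 0.22), Cd93 (−3.17 ± 0.28), Gfi1 (−3.12 ± 0.27), Pstpip2 (−3.09 ± 0.22), Myb (−2.84 ± 0.23) and the cation channel gene Trpm5 (−2.80 ± 0.24). All of these had an edgeR adjusted p of at most 1.09e-05. Cd86 was higher in CD11cint cells, at 55.8 ± 3.29 against 39.6 ± 3.32 CPM (0.49 ± 0.07, edgeR adjusted p = 2.59e-05). H2-Ab1, an MHC class II chain, was at 1834 ± 337 against 1666 ± 94.2 CPM and C3 at 4.44 ± 0.52 against 5.03 ± 1.15 CPM, neither past the test (edgeR adjusted p = 0.318 and 0.669). March1 was lower (−0.24 ± 0.07, edgeR adjusted p = 0.0183). The March1 call ended in the fit of the compared groups alone (0.0747) and without March1-/- B cell library 2 (0.0936).

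Lists of other B cell states mostly fell in CD11cint cells. All 5 B-1 genes fell (camera adjusted p = 9.84e-12, and 0.000879 with an estimated correlation), with Spn, which encodes CD43, at −2.65 ± 0.15 and Zbtb32 at −1.54 ± 0.17. Of 7 plasma cell genes 4 fell (camera adjusted p = 0.000266, and 0.0218 with an estimated correlation). Of 8 germinal centre genes 5 fell, among them Rgs13, Bcl6 (−0.99 ± 0.18) and Neil1 (−0.50 ± 0.11), but camera's adjusted p of 6.64e-05 became an adjusted p = 0.11 with an estimated correlation. Each of these counts was the same adjusted over the list alone. Of 15 pan B genes 4 rose, 2 fell and 9 did not pass the test (6 rises and 2 falls adjusted over the list alone). Of 6 genes of CD11c+ T-bet+ B cells 3 fell, 4 adjusted over the list alone, among them Tbx21, which encodes T-bet (−1.12 ± 0.17), and neither this list nor the pan B list was called by limma's camera (adjusted p = 0.0516 or above).

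Genes of cDC1 were higher in CD11cint cells than in B cells, at levels far below those of cDC1. Of 14 genes 7 rose and none fell, with 8 rises adjusted over the list alone (camera adjusted p = 3.42e-06, and 0.0182 with an estimated correlation). Tlr3, the receptor for double-stranded RNA, was at 50.03 ± 5.36 against 14.2 ± 5.23 CPM in B cells. Xcr1, the receptor for XCL1, was at 3.52 ± 0.47 against 1.65 ± 0.35 CPM. Cd8a rose by 1.60 ± 0.18 and Id2 by 0.79 ± 0.13 on the log2 scale. Markers of T and NK cells were lower than in the B cell libraries. Of 11 T cell genes 10 fell, with Lck at 25.0 ± 1.10 against 61.9 ± 7.88 CPM (camera adjusted p = 1.58e-06, and adjusted p = 0.167 with an estimated correlation). Of 7 NK cell genes 6 fell and 1, the perforin gene Prf1, rose (camera adjusted p = 0.00186, and adjusted p = 0.476 with an estimated correlation). Of 7 plasmacytoid dendritic cell genes 3 fell, 4 adjusted over the list alone (camera adjusted p = 0.0168, and adjusted p = 0.478 with an estimated correlation). This list was not called without CD11cint library 3 (camera adjusted p = 0.05). Of 12 immediate early genes, which dissociation of tissue is known to induce, 4 fell, 6 adjusted over the list alone, with Egr1 at −2.00 ± 0.29 (camera adjusted p = 0.00354, and adjusted p = 0.503 with an estimated correlation). No call by camera was made in CD11cint cells against B cells for the lists of pan cDC, cDC2, spleen macrophage, monocyte, neutrophil or erythroid genes (adjusted p = 0.0804 or above). The same held for the lists of MHC class I and class II presentation, costimulation, complement, MARCH ligases, Notch, interferon response, unfolded protein response and proliferation (adjusted p = 0.131 or above). Within them, Cd274, which encodes PD-L1, rose by 0.72 ± 0.09, the Notch target genes Hes1 and Dtx1 rose by 1.02 ± 0.09 and 1.34 ± 0.18, and Cd55, which encodes a complement regulator, fell by 1.45 on the log2 scale.

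**Figure D2:**
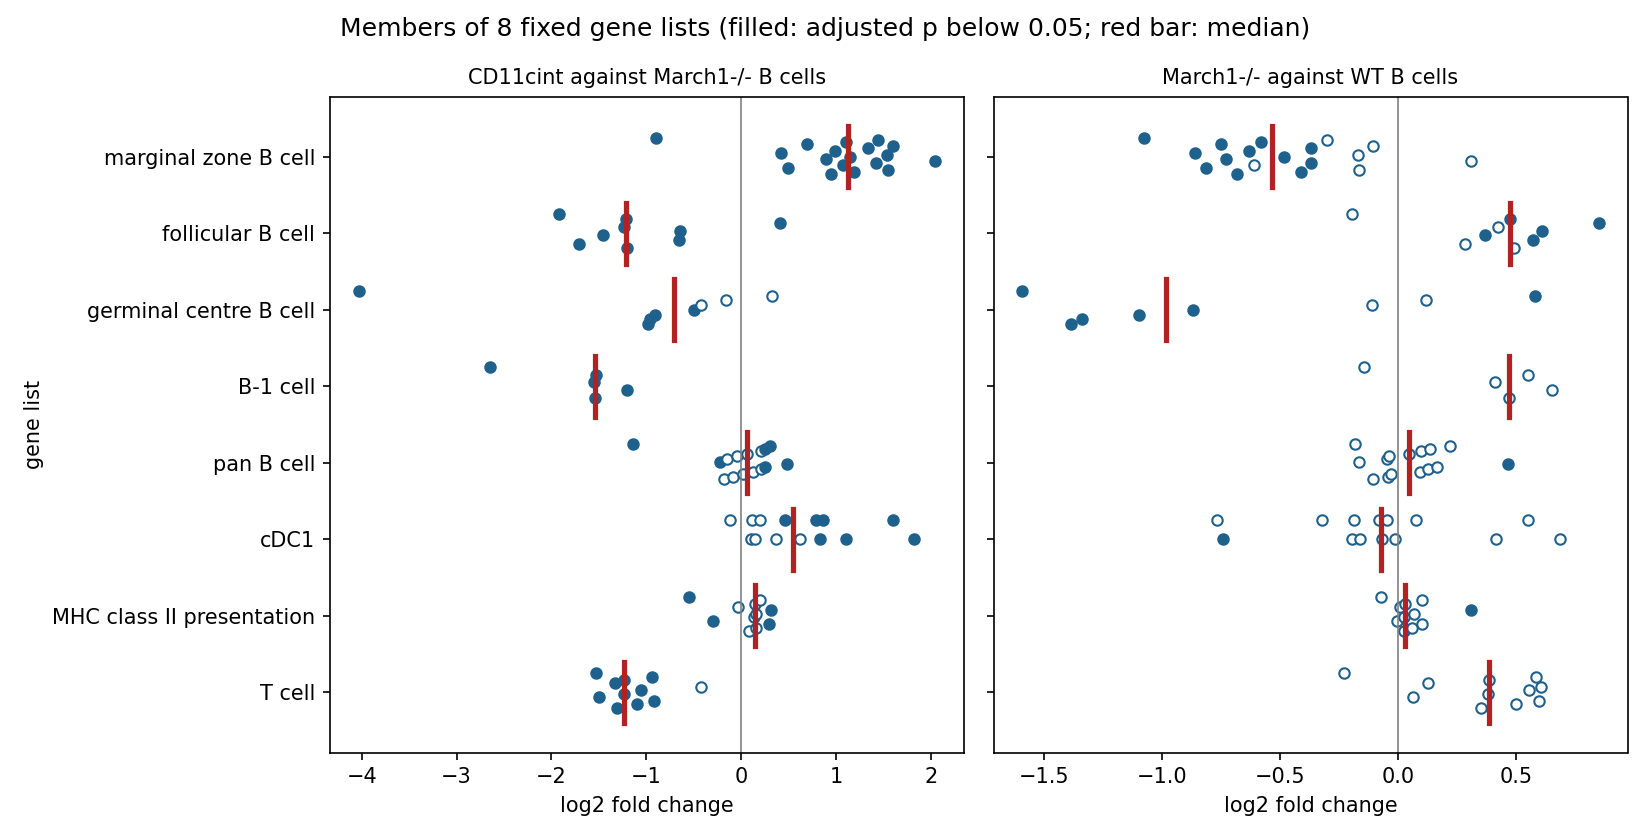
Log2 fold change of each member (points) and the median (bar) of 8 fixed gene lists, for CD11cint cells against March1-/- B cells (left) and for March1-/- against WT B cells (right); filled points passed an adjusted p of 0.05. The marginal zone list has a median of 1.13 on the left and −0.53 on the right, and the follicular list −1.21 and 0.47.

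Against cDC1 of the same genotype, CD11cint cells had B lineage RNA and little cDC1 RNA. All 15 pan B genes rose (median log2 fold change 5.59; camera adjusted p = 2.32e-49, and 4.57e-06 with an estimated correlation), with Cd79a, a signalling chain of the B cell receptor, at 6.33 ± 0.14 and Ms4a1, which encodes CD20, at 5.26 ± 0.09. All 14 cDC1 genes and all 5 pan cDC genes fell (camera adjusted p = 3.31e-25 and 1.08e-11, and 2.83e-05 and 0.00177 with an estimated correlation). Xcr1 fell by 7.80 on the log2 scale and Zbtb46, a transcription factor of conventional dendritic cells, by 6.63. Among the largest rises that the naming rule allows were Ackr2, Kcnk5, Cr2, Fcrl5, Cxcr5, Tsga13, Rxfp1 and Adam28, with log2 fold changes of 6.33 to 6.93. Adam28 was at 0.10 ± 0.05 CPM in March1-/- cDC1. Among the largest falls under the same rule were Tlr11 (−8.28 ± 0.11), Itga8 (−8.13 ± 0.15), Fzd1 (−8.00 ± 0.14) and Ocstamp (−7.98 ± 0.15). Cyp7b1, H2-M5, Cd209e, Clec1a, Nlrp1c-ps and Ltbp2 fell as well and were near 0 counts in CD11cint cells. All of these had an edgeR adjusted p of at most 7.97e-12. H2-Ab1 was at 6969 ± 368 CPM in March1-/- cDC1 and fell by 1.93 on the log2 scale, and Cd86 fell by 2.74. Of 11 MHC class II genes 8 fell and 2, H2-DMb2 and H2-Ob, rose, and of 14 MHC class I genes 12 fell and 1, H2-K1, rose. For both, camera's adjusted p was 0.0473, which became an adjusted p = 0.744 for class II and 0.695 for class I with an estimated correlation. In total 13534 genes were called by edgeR's quasi-likelihood test, 6849 higher and 6685 lower in CD11cint cells. Of these, 6261 changed at least 2-fold.

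In the same comparison 14 of 18 marginal zone genes rose and 4 fell (camera adjusted p = 2.93e-09, and adjusted p = 0.0698 with an estimated correlation). Of 9 follicular genes 7 rose and 1, Klf2, fell (camera adjusted p = 3.65e-06, and 0.0118 with an estimated correlation). All 7 cDC2 genes fell (camera adjusted p = 0.000708, and adjusted p = 0.122 with an estimated correlation). Of the 6 genes of CD11c+ T-bet+ B cells 4 fell and 1 rose (camera adjusted p = 0.0473, and adjusted p = 0.576 with an estimated correlation). These counts and those of the pan B, cDC1, pan cDC and MHC lists were the same adjusted over the list alone. The class I, class II and CD11c+ T-bet+ calls were also lost under several single-library omissions, for example without CD11cint library 3 (camera adjusted p = 0.0579 for each). Both MHC calls were lost with RLE factors (camera adjusted p = 0.0502 for each). The CD11c+ T-bet+ call was lost with limma-voom (0.0965) and with a replicate block within genotype (0.0589). No other list was called in CD11cint cells against cDC1 (camera adjusted p = 0.086 or above). All 12 immediate early and all 15 proliferation genes fell past edgeR's test, also adjusted over the list alone (camera adjusted p = 0.086 and 0.271). Of all tested genes 72.34% were called in this comparison.

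The place of CD11cint cells between the 2 reference populations was measured on 1531 axis genes chosen in the WT libraries, 637 higher in B cells and 894 higher in cDC1. On this scale 0 is the WT cDC1 mean and 1 the WT B cell mean. CD11cint libraries stood at 0.976 ± 0.00474, March1-/- B cells at 1.004 ± 0.00778 and March1-/- cDC1 at 0.021 ± 0.0127 (n = 4 each). All 4 CD11cint libraries lay below all 4 March1-/- B cell libraries (exact permutation test, two-sided, p = 0.0286, the smallest that 70 assignments allow) and above the March1-/- cDC1 libraries (exact permutation p = 0.0286). The same order was seen among the B-high genes (0.964 ± 0.0081 against 1 ± 0.009) and the cDC1-high genes (0.985 ± 0.00504 against 1.006 ± 0.00928), each with an exact permutation p = 0.0286. These assignments leave out that March1-/- B cell and CD11cint libraries of the same number deviated together. Within the 4 numbered pairs the CD11cint library was lower each time (mean difference −0.0277 ± 0.00943), and sign flips within pairs gave an exact permutation p = 0.125, the smallest that 4 pairs allow, for all axis genes, the B-high and the cDC1-high genes. Without CD11cint library 1 the difference from B cells had an exact permutation p = 0.0571.

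The summed level of 437 cDC1-specific genes in CD11cint libraries was 2.53% ± 0.0405 of that in March1-/- cDC1 (n = 4). The background measured in the same way was 2.20% ± 0.206 in March1-/- B cells and 2.14% ± 0.179 in WT B cells. CD11cint libraries exceeded March1-/- B cells by 0.326 percentage points (exact permutation test, two-sided, p = 0.0286). The CD11cint library was higher in all 4 numbered pairs, and sign flips within pairs gave an exact permutation p = 0.125, the smallest that they allow. The difference between the 2 B cell groups did not pass the test (exact permutation p = 0.657). On the 222 genes with the highest specificity the levels were 1.05% ± 0.101 and 0.691% ± 0.0365 (exact permutation p = 0.0286, and 0.125 within pairs). The difference was no longer past 0.05 as a median of per-gene percentages (1.61% against 1.495%, exact permutation p = 0.171) or with RLE scaling (2.51%, exact permutation p = 0.0571). It was not past 0.05 either with any 1 of the 4 CD11cint libraries left out (exact permutation p = 0.0571 each time, at 2.515% to 2.545%).

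**Figure D3:**
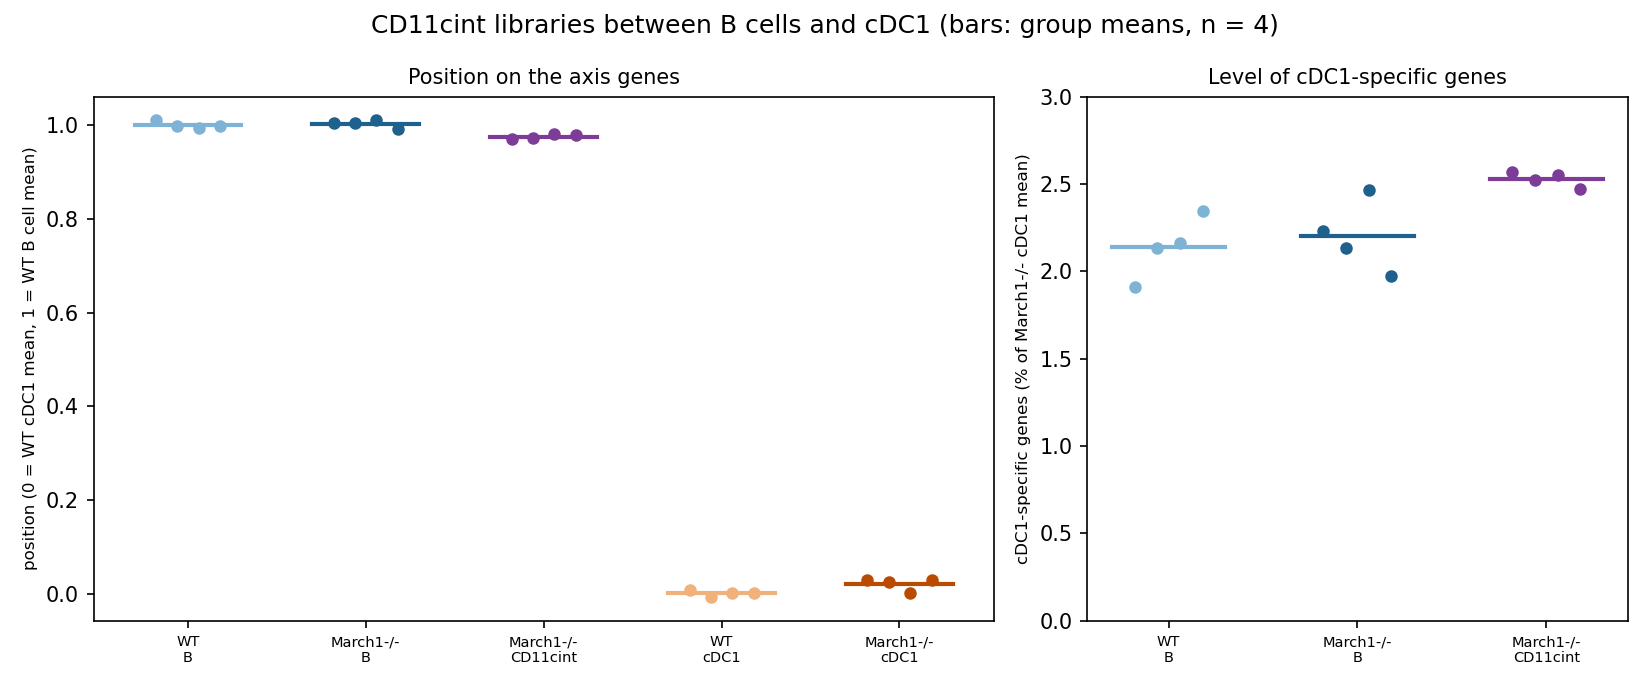
Position of each of the 20 libraries between WT cDC1 (0) and WT B cells (1) over 1531 axis genes (left), and the level of 437 cDC1-specific genes in B cell and CD11cint libraries in percent of the March1-/- cDC1 mean (right); points are libraries and bars are group means (n = 4). The CD11cint libraries sit at 0.970 to 0.981 on the left and at 2.47% to 2.57% on the right.

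B cells labelled March1-/- were compared with WT B cells to see how the genotype changed the B cell population. Marginal zone genes were lower: 12 of 18 fell and 6 did not pass the test, with a median log2 fold change of −0.53 (14 falls and 1 rise adjusted over the list alone; camera adjusted p = 7.19e-19, and 0.0125 with an estimated correlation). Sema7a was at 56.4 ± 6.88 against 102.4 ± 17.4 CPM (−0.86 ± 0.10, edgeR adjusted p = 1.48e-05), Asb2 at 16.9 ± 3.51 against 35.7 ± 8.77 CPM, Cd9 at 26.1 ± 3.16 against 40.5 ± 5.34 CPM and S1pr3 at 67.8 ± 12.2 against 119.1 ± 23.8 CPM. Cr2 was at 1399 ± 369 against 2095 ± 199 CPM (−0.58 ± 0.14, edgeR adjusted p = 0.0192). The Cr2 call was lost without any 1 of March1-/- B cell libraries 1, 3 and 4 or WT B cell libraries 1 and 4 (edgeR adjusted p = 0.0625, 0.0869, 0.0646, 0.0703 and 0.0663) and in the fit of the compared groups alone (0.0999). Follicular genes were higher: 5 of 9 rose and none fell, 7 rises adjusted over the list alone (camera adjusted p = 1.46e-08, and 0.00585 with an estimated correlation). Vpreb3 rose from 24.5 ± 2.42 to 44.2 ± 4.71 CPM, Ighd from 908.9 ± 135 to 1387 ± 110 CPM and Fcer2a from 330.5 ± 50.2 to 458.8 ± 30.7 CPM (edgeR adjusted p = 1.67e-05, 0.00194 and 0.00861). Of 8 germinal centre genes 5 fell and 1, Rgs13, rose, the same counts adjusted over the list alone (camera adjusted p = 3.19e-07, and 0.0475 with an estimated correlation). The Rgs13 call was lost without March1-/- B cell libraries 1, 3 or 4 or WT B cell libraries 1, 3 or 4 (edgeR adjusted p = 0.0632, 0.12, 0.0686, 0.0615, 0.0619 and 0.0971). Among the falls were Gcsam (−1.59 ± 0.22), S1pr2 (−1.34 ± 0.25) and Fas (−0.87 ± 0.15).

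In total 890 genes were called between the B cells of the 2 genotypes by edgeR's quasi-likelihood test, 433 higher and 457 lower in March1-/-, with 70 and 108 of at least 2-fold. The count was 590 without March1-/- B cell library 1, 574 without library 3, and 591 and 592 without WT B cell libraries 1 and 4. Among the genes the naming rule allows, the largest rises were Wnt10a (1.76 ± 0.19), Ifi30, a thiol reductase of the antigen-processing compartment (1.67 ± 0.08), Gsr (1.5 ± 0.11), Nyx (1.42 ± 0.24), Zfp868 (1.42 ± 0.05), Cd93 (1.22 ± 0.25), Pstpip2 (1.18 ± 0.18), Wdfy1 (1.16 ± 0.12), Actn1 (1.02 ± 0.16) and Trpm5 (1.01 ± 0.21), with edgeR adjusted p of 0.0054 or less. Ifi30 was at 493.2 ± 15.7 CPM against 155.4 ± 10.3 CPM. Under the same rule the largest falls were Mid1 (−2.40 ± 0.22), Lpar2, a receptor for lysophosphatidic acid (−2.21 ± 0.11), Ifi208 (−2.01 ± 0.12), AW011738 (−1.18 ± 0.14), Ffar2 (−1.16 ± 0.16), Asb2, Zfp968 (−1.08 ± 0.25), Entpd4 (−1.05 ± 0.10), Entpd4b (−1.04 ± 0.10) and Zfp965 (−1.01 ± 0.23), with edgeR adjusted p of 0.0117 or less. Ifi30, Zfp868 and Lpar2 lie 4.29, 3.14 and 3.35 Mb from March1 on chromosome 8, in a stretch where genotype calls were concentrated. Gsr lies 31.9 Mb from March1, in another stretch with many calls. Mid1 has an annotated pseudogene copy on chromosome Y, and Entpd4 with Entpd4b and Zfp965 with Zfp968 are near-identical pairs, so the gene that moved is uncertain for these 5. Zfp968 was not called without March1-/- B cell library 1 (edgeR adjusted p = 0.0531).

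Most genes of antigen presentation did not pass the test in March1-/- B cells. Of 11 MHC class II genes 1, H2-Ob, rose (0.31 ± 0.07, edgeR adjusted p = 0.00637), also when adjusted over the list alone. H2-Ab1 was at 1666 ± 94.2 against 1633 ± 29.7 CPM (0.03 ± 0.09, edgeR adjusted p = 0.933). Cd86, whose protein MARCH1 is known to target, fell from 51.2 ± 3.49 to 39.6 ± 3.32 CPM (−0.37 ± 0.07, edgeR adjusted p = 0.00326). C3, Itgax, Cd24a, Xcr1 and Cd8a did not pass the test (edgeR adjusted p = 0.0671 or above). Of the 6 genes of CD11c+ T-bet+ B cells 2 fell, 3 adjusted over the list alone, with the chemokine receptor gene Cxcr3 at 3.22 ± 0.35 against 8.30 ± 1.15 CPM (camera adjusted p = 1.91e-05, and adjusted p = 0.086 with an estimated correlation). Of 15 proliferation genes 2 fell, 12 adjusted over the list alone (camera adjusted p = 1.96e-07, and adjusted p = 0.493 with an estimated correlation). The 11 T cell genes were called as higher together, with none past the test alone and 1, Lck, adjusted over the list alone (camera adjusted p = 0.0333, and adjusted p = 0.721 with an estimated correlation). That call was lost with RLE scaling (0.0503) and without March1-/- B cell libraries 1 and 2 or WT B cell libraries 1 and 3 (0.234, 0.0809, 0.134 and 0.0677). No other list was called (camera adjusted p = 0.0612 or above).

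The cDC1 of the 2 genotypes were compared in the same way. B lineage transcripts were higher in cDC1 labelled March1-/-. Of 15 pan B genes 11 rose and none fell, 13 rises adjusted over the list alone (median 0.85; camera adjusted p = 3.07e-59, and 5.48e-05 with an estimated correlation). Their levels stayed low: Pou2af1 was at 10.6 ± 0.81 against 3.82 ± 0.66 CPM, Blk at 10.7 ± 1.16 against 4.17 ± 0.75 CPM, Ebf1 at 3.76 ± 0.59 against 1.29 ± 0.08 CPM and Pax5 at 17.7 ± 2.49 against 6.29 ± 1.24 CPM (edgeR adjusted p of 7.42e-07 or less). Cr2 was at 36.2 ± 5.61 against 11.9 ± 1.28 CPM (1.60 ± 0.16, edgeR adjusted p = 1.1e-06). The sum of 329 B-specific genes made up 3.14% ± 0.272 of its level in March1-/- B cells, against 2.55% ± 0.191 in WT cDC1 (difference 0.593 percentage points, exact permutation test, two-sided, p = 0.0286). Genes of dendritic cells that fell included Itgae, which encodes CD103 (33.9 ± 8.86 against 104.9 ± 18.4 CPM), Il12b, the p40 chain of interleukin 12 (11.5 ± 2.49 against 43.4 ± 6.20 CPM), and the chemokine gene Ccl22 (19.2 ± 4.15 against 54.0 ± 3.97 CPM), with edgeR adjusted p of 9.15e-07, 8.64e-08 and 0.00014. In total 536 genes were called by edgeR's quasi-likelihood test, 286 higher and 250 lower in March1-/-, with 110 and 80 of at least 2-fold. The count was 437 without the genes at least 16-fold higher in WT B cells than in WT cDC1, chosen after seeing the data.

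The other largest rises in March1-/- cDC1, among the genes the naming rule allows, were Lzts1 (4.17 ± 0.20), Ace, which encodes angiotensin-converting enzyme (3.34 ± 0.22; 41.9 ± 11.6 against 4.12 ± 1.06 CPM), Ddit4 (1.65 ± 0.25), Notch3 (1.28 ± 0.25), Zfp868 (1.28 ± 0.06) and Pacsin1 (1.17 ± 0.22), with edgeR adjusted p of 0.00404 or less. Pacsin1 was not called in the fit of the compared groups alone (0.119). The other largest falls under the same rule were Hpgd, an enzyme that inactivates prostaglandins (−3.05 ± 0.26), Synpo2 (−2.26 ± 0.24), H2-M2 (−1.89 ± 0.19), Mid1 (−1.66 ± 0.22), Asprv1 (−1.53 ± 0.29), Ankrd33b (−1.33 ± 0.15) and Glipr2 (−1.28 ± 0.16), with edgeR adjusted p of 0.00332 or less. Asprv1 was not called by DESeq2 (0.0988). Lzts1, Zfp868 and Hpgd lie 2.66, 3.14 and 9.3 Mb from March1 on chromosome 8, and Ccl22 lies 28.3 Mb from it. Of 14 cDC1 genes only Itgae passed the test, over all genes and adjusted over the list alone (camera adjusted p = 0.000995, and adjusted p = 0.0844 with an estimated correlation). None of 11 MHC class II genes passed the test over all genes or adjusted over the list alone (camera adjusted p = 0.0822). H2-Ab1 was at 6969 ± 368 against 7576 ± 387 CPM and Cd86 at 372.5 ± 23.7 against 402.5 ± 25.9 CPM (edgeR adjusted p = 0.788 and 0.68). Of 9 costimulation genes 2 fell, also adjusted over the list alone, Cd83 (−0.41 ± 0.09) and Cd40 (−0.38 ± 0.09). The Cd40 call was lost without March1-/- cDC1 libraries 1 or 4 (edgeR adjusted p = 0.0525 and 0.0553).

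Among the remaining lists in cDC1, 6 of 18 marginal zone genes rose, 8 rises and 1 fall adjusted over the list alone (camera adjusted p = 4.19e-10, and adjusted p = 0.0734 with an estimated correlation). Of 12 complement genes 2 rose, also adjusted over the list alone: Cr2, and C4b at 0.778 ± 0.286 against 0.314 ± 0.0549 CPM (camera adjusted p = 0.000576, and 0.0134 with an estimated correlation). The C4b call was lost with limma-voom (0.109) and DESeq2 (0.0501) and without any 1 of 7 of the 8 libraries, all but March1-/- cDC1 library 2. Of 15 interferon response genes 1 fell, with 8 falls and 1 rise adjusted over the list alone (camera adjusted p = 4.44e-05, and adjusted p = 0.0734 with an estimated correlation). The lists of costimulation, follicular, proliferation, immediate early and Notch genes had camera adjusted p of 0.0408, 0.0408, 0.0408, 0.0441 and 0.0454, and an adjusted p = 0.0844, 0.245, 0.73, 0.73 and 0.41 with an estimated correlation. Of 9 follicular genes 2 rose and 1 fell, 3 and 1 adjusted over the list alone, and of 11 Notch genes 1 rose, the same adjusted over the list alone. No proliferation or immediate early gene passed either test. Each of these 5 list calls was also lost when single libraries were left out, for example without WT cDC1 library 4 (camera adjusted p = 0.0531, 0.0764, 0.261, 0.292 and 0.0854). No other list was called (camera adjusted p = 0.0822 or above).

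Whether the genotype acted differently in the 2 cell types was tested with an interaction term, taken as the change in cDC1 minus the change in B cells. It called 441 genes by edgeR's quasi-likelihood test, 278 with a positive and 163 with a negative difference. DESeq2 called 679. The 10 genes that the naming rule takes by smallest adjusted p were Gsr (−1.75 ± 0.14), Mfhas1 (1.74 ± 0.14), Ifi30 (−1.42 ± 0.12), Pou2af1 (1.37 ± 0.12), Acsl1 (1.04 ± 0.09), Blk (1.46 ± 0.14), Cr2 (2.18 ± 0.21), S1pr3 (2.54 ± 0.26), Ebf1 (1.45 ± 0.16) and Cxcr3 (1.33 ± 0.15), with edgeR adjusted p of 1.49e-05 or less. Ifi30 and Acsl1 lie 4.29 and 19.1 Mb from March1 on chromosome 8, and Gsr and Mfhas1 lie 31.9 and 29.9 Mb from it. Ifi30, for example, was at 518.8 ± 27.9 against 436.6 ± 40.8 CPM in cDC1 but rose more than 3-fold in B cells. Of 15 pan B genes 8 had a positive difference past the test, 11 adjusted over the list alone. Of 18 marginal zone genes 11 did, 14 adjusted over the list alone. Both lists kept their call with an estimated correlation (camera adjusted p = 3.02e-38 and 1.85e-38, and 0.000396 for both with an estimated correlation), as did the complement list (0.000424 and 0.00963). The pan B list had a median log2 fold change of 0.85 in cDC1 and 0.04 in B cells. B lineage RNA in the March1-/- cDC1 libraries would also give positive differences for B lineage genes. A response of the cDC1 themselves cannot be told apart from it. March1 had a difference of −0.41 ± 0.10 (edgeR adjusted p = 0.0323), a call that was lost in 11 of the 16 fits that left out 1 library.

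Of the 433 and 286 higher genes 48 were shared, against 6.62 for independent lists (Fisher's exact test, one-sided, p = 1.65e-27). Of the 457 and 250 lower genes 57 were shared, against 6.11 (Fisher's exact test, one-sided, p = 6.81e-39). In opposite directions 23 genes were called, against 12.8. The comparisons share no library, but Fisher's test takes the B cell and cDC1 libraries of a number to vary independently, whereas within a genotype same-numbered libraries deviated together (Pearson's r across genes 0.0893 to 0.315 in WT and 0.088 to 0.202 in March1-/-). Both cell types of a number were therefore moved together between the genotypes, in 35 splits. At an unadjusted p under 0.05 the real split shared 369 genes in the same direction, 2.32 times the number for independent lists, and 21 of the 35 splits, the real one included, had a ratio as high (1.24 to 10.2 in the others). Among adjusted calls the other splits shared 0 genes, but they called at most 16 in B cells and 6 in cDC1. Across all genes, which are not independent replicates, Pearson's correlation of the 2 log2 fold changes was 0.155, and 3 of the 35 splits had one as high. With chromosome 8 left out, 34 and 47 genes were shared, against 5.37 and 5.13.

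Genotype calls were concentrated on chromosome 8, around March1 and in a stretch away from it. Within 20 Mb of the gene, 56 of 334 tested genes (16.8%) were called in B cells, against 834 of 18375 others (4.54%), with an odds ratio of 4.24 (95% interval 3.09 to 5.72; Fisher's exact test, one-sided, p = 1.27e-16). In cDC1 it was 42 (12.6%) against 493 (2.68%), with an odds ratio of 5.22 (3.64 to 7.33; Fisher's exact test, one-sided, p = 6.54e-16). Fisher's test takes genes as independent, which neighbouring genes need not be, so these p-values may be too small and the intervals too narrow. By chromosome, calls made up 9.96% of tested genes in B cells and 6.85% in cDC1 on chromosome 8, and 3.45% to 5.97% and 1.35% to 4.05% on the other autosomes and X. Chromosome Y had a higher share than chromosome 8. Reads can be shared between copies there, so the number of separate changes is uncertain. Of its 11 tested genes 5 (45.5%) were called as lower in March1-/- in each cell type. These were Mid1-ps1, Gm21860, Gm47283, Gm21742 and Gm21748, between 90753057 and 90844040 on chromosome Y. Their B cell calls held in every fit that left out 1 library. In cDC1 those of Gm21860, Gm47283 and Gm21748 were lost in 4, 5 and 4 of 8 such fits (edgeR adjusted p = 0.0507 to 0.106), and that of Gm47283 in the fit of the compared groups alone (0.14). On chromosome 8 the stretch from 70000001 to 75000000 held 34 of the B cell calls and 26 of the cDC1 calls among 118 genes. Outside the 20 Mb window, 30000001 to 35000000 held 8 and 5 calls among 23 genes, and 35000001 to 40000000 held 6 and 6 among 11. The stretch that holds the start of March1, 65000001 to 70000000, had 6 and 9 among 33. Next to it, 60000001 to 65000000 had 1 and 0 among 13, so the calls were uneven around the gene. Of 18 genes near March1 called in both cell types, 12 placed every March1-/- library on the same side of every WT library of its cell type, with the CD11cint libraries counted with the B cells. Of these, 6 were higher and 6 lower in March1-/-. These genes had been chosen by their calls, so no chance share applies to that count. Among all tested genes, called or not, 16 of 334 near March1 (4.79%) and 63 of 18375 others (0.343%) separated the libraries in this way. For a gene with no difference this occurs in 0.00577% of 34650 assignments of independent libraries. If all libraries of 1 number and genotype were a single pool, it would occur in up to 2.86% of 70 assignments of 8 pools. Zfp868 (69610857 to 69625548) was at 25.5 ± 0.76 and 18.97 ± 0.94 CPM in WT B cells and cDC1 and at 68.1 ± 2.93, 45.9 ± 1.53 and 64.4 ± 2.82 CPM in March1-/- B cells, cDC1 and CD11cint cells. Haus8, a subunit of the augmin complex of the spindle (71248561 to 71272934), fell by 0.88 in B cells and by 0.92 in cDC1 on the log2 scale. Lpar2 (69822429 to 69831102) fell in both as well, and Jak3, a kinase of cytokine receptors (71676296 to 71690575), rose by 0.44 ± 0.08 and 0.62 ± 0.08. These genes and those of chromosome Y were singled out after their values were seen.

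**Figure D4:**
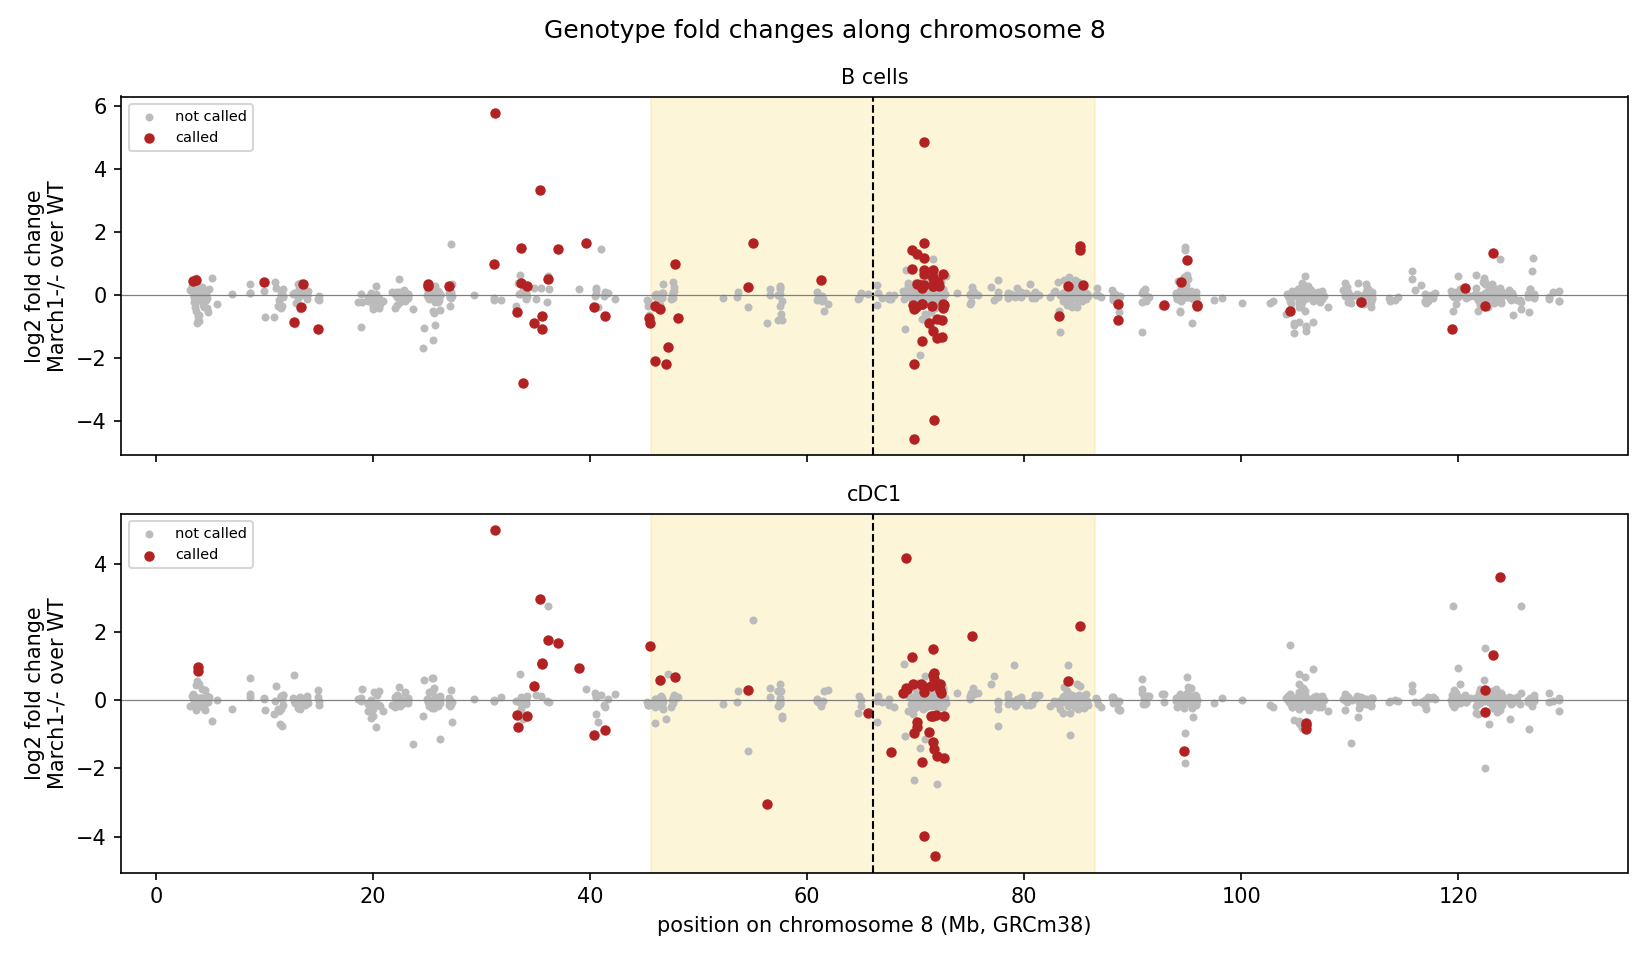
Log2 fold change of March1-/- against WT along chromosome 8 (position in Mb, GRCm38) for B cells (top) and cDC1 (bottom), with 1 point per tested gene and called genes in colour; the dashed line marks March1 and the shaded band 20 Mb on either side. The band holds 56 called genes in B cells and 42 in cDC1.

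As a reference for these comparisons, cDC1 and B cells differed in most genes in both genotypes. In WT, 13298 genes were called by edgeR's quasi-likelihood test, 6526 higher and 6772 lower in cDC1, and in March1-/- 13384, 6673 higher and 6711 lower. All 14 cDC1 genes and all 5 pan cDC genes rose and all 15 pan B genes fell in cDC1 of either genotype, also adjusted over the list alone, and all kept their call with an estimated correlation (camera adjusted p of 0.00309 or less). Of 9 follicular genes 7 fell and 1 rose in WT and 8 fell in March1-/- (camera adjusted p = 0.00521 and 0.00204 with an estimated correlation). The marginal zone, cDC2, MHC class I and MHC class II lists were called by camera in both genotypes but had an adjusted p = 0.159 or above with an estimated correlation. No other list was called in cDC1 against B cells (camera adjusted p = 0.127 or above). Among the genes most specific to WT cDC1 were Tlr11 (log2 fold change 9.82 ± 0.12), Gpr141b (10.14 ± 0.21), Cd8a (9.90 ± 0.19) and Cd207, which encodes langerin (10.22 ± 0.25), and among those most specific to WT B cells Cr2 (−7.45 ± 0.19), Fcmr, the receptor for IgM (−7.36 ± 0.16), Cd79a (−7.32 ± 0.15) and Pax5 (−7.28 ± 0.17) (edgeR adjusted p of 2.55e-19 or less). C3 was lower in cDC1 by 0.63 on the log2 scale in WT and 0.71 in March1-/- (edgeR adjusted p = 0.0327 and 0.0175). The WT call for C3 was lost in the fit of the compared groups alone (0.134) and without WT B cell libraries 3 or 4 or WT cDC1 libraries 1 or 2 (edgeR adjusted p = 0.187, 0.0738, 0.126 and 0.098). The March1-/- call was lost without B cell library 2 (0.0685) or cDC1 library 1 (0.0524).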

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

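The tests that weigh explanations in the last 3 paragraphs of this part, and the splits that moved both cell types of a number together, were chosen after the results were seen. The interaction, the tests of lists, the count of calls within 20 Mb of March1 and the other splits were planned.

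In 26 of 398 groups of 4 libraries looked at (6.53%), 1 library lay far from the others by Dixon's ratio, where chance gives about 1 in 20. Values are in CPM, with the range of the other 3 libraries in parentheses. In the March1-/- B cells Sorbs2 was at 5.441 in library 2 (3.079 to 3.309), Neil1 at 16.14 in library 2 (21.72 to 22.7), Bcl6 at 32.68 in library 4 (59.52 to 63.55) and Ighg2c at 140.7 in library 3 (10.96 to 29.42). In the WT B cells Cd86 was at 56.39 in library 1 (49.19 to 49.54), H2-Ob at 571.9 in library 1 (647.5 to 651.7) and S1pr2 at 8.566 in library 2 (6.504 to 6.791). In CD11cint library 1, Cr2 was at 2494 (3263 to 3419), S1pr3 at 225.5 (198.3 to 199.9), Ighm at 7452 (6100 to 6279) and H2-M5 at 0.0705 (0 in the others). In CD11cint library 4, Cd55 was at 129.3 (124.1 to 124.7), Ackr2 at 107.4 (81.2 to 84.07) and Cyp7b1 at 0.0354 (0 in the others), and in library 3 Zbtb46 was at 2.491 (2.829 to 2.859). In March1-/- cDC1 library 3, H2-K1 was at 1461 (1389 to 1392), Ankrd33b at 8.228 (5.261 to 5.675), Glipr2 at 14.52 (6.893 to 8.101) and Eif2s3y at 31.96 (20.73 to 21.38), in library 4 H2-Ob was at 446 (385.4 to 388.7), and in library 1 Gm21742 was at 1.28 (0.6424 to 0.7314). The position of March1-/- cDC1 library 3 was 0.00215 (0.0248 to 0.0289). In WT cDC1, Il12b was at 34.24 in library 1 (45.63 to 47.93), Lzts1 at 0.920 in library 1 (0.529 to 0.593), Mfhas1 at 14.38 in library 2 (16.42 to 16.73) and Ace at 5.699 in library 4 (3.456 to 3.792).

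The change with genotype differed between cDC1 and B cells, by edgeR's interaction term, for 441 genes in all and for 34 of the 83 genes named for the genotype comparisons or the interaction. Values are the log2 change in cDC1 minus that in B cells. Among B lineage genes they were 1.37 for Pou2af1, 1.46 for Blk, 1.45 for Ebf1 and 1.52 for Pax5, which rose in cDC1. B lineage RNA in the March1-/- cDC1 libraries would give such values as well. Cxcr3, Gcsam and S1pr2, which fell in B cells and were higher in cDC1 than in B cells in WT, had 1.33, 1.46 and 1.41. Marginal zone genes had 0.62 for Sema7a, 1.14 for Asb2, 0.76 for Cd9, 2.54 for S1pr3 and 2.18 for Cr2. Of the genes with the largest changes in B cells, Ifi30 had −1.42, Gsr −1.75, Pstpip2 −1.33, Actn1 −1.20, Lpar2 1.24, AW011738 1.31, Entpd4 1.16, Entpd4b 1.16 and H2-Ob −0.41. Of those with the largest changes in cDC1, Ccl22 had −1.94, Lzts1 3.38, Ace 3.33, Ddit4 1.60, Notch3 2.44, Pacsin1 1.23, Hpgd −2.17, Ankrd33b −1.34, Glipr2 −1.30 and Cd83 −0.67. March1 had −0.41, Mfhas1 1.74 and Acsl1 1.04.

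Lists that limma's camera called in the interaction are given with the adjusted p at the preset correlation and then with an estimated correlation. The pan B list had 3.02e-38 and 0.000396, the marginal zone list 1.85e-38 and 0.000396, and the complement list 0.000424 and 0.00963, with 2 of its genes past edgeR's test (4 adjusted over the list alone). The other calls were lost with an estimated correlation: germinal centre (0.000211, then an adjusted p = 0.153; 2 genes, 3 adjusted over the list alone), CD11c+ T-bet+ (7.08e-06, then 0.061; 1 gene and 2), interferon response (0.00154, then 0.182; 2 falls and 3), proliferation (2.83e-10, then 0.232; 0 genes and 11) and immediate early genes (0.00138, then 0.461; 1 fall and 1). For the Notch list it was 0.0119, then 0.232 (2 genes and 2), and 0.0701 without March1-/- B cell library 4. For MHC class II it was 0.0114, then 0.47 (1 fall and 1), and 0.0592 without WT cDC1 library 1. For plasmacytoid dendritic cells it was 0.0193, then 0.461 (1 gene and 1), and 0.0673, 0.167, 0.0564 and 0.0562 without WT B cell libraries 2 or 4 or WT cDC1 libraries 2 or 3.

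Other splits of the same libraries were fitted in the same way, with 35 splits per comparison and 100 drawn for the interaction. For genotype, 1 split, the real one, called as many genes. In B cells no pairing of the genotypes by number was seen, and 1 of 35 splits is a share of 2.86%, the lowest possible. This counts against chance only if the libraries are independent, which the labels do not say. In cDC1 same-numbered libraries of the genotypes may be paired. The 8 splits that part all 4 pairs are too few there for a share under 0.05. The same would hold in B cells if the B cells and cDC1 of a number came from the same pool. The real counts and the highest of the other splits were 890 and 21 in B cells, 536 and 19 in cDC1, and 441 and 298 for the interaction. Those splits of the interaction leave out that B cell and cDC1 libraries of a number deviated together within a genotype. With both cell types of a number moved together, 1 of 35 splits, the real one, called as many genes for the interaction, and the highest other called 1. If the numbers pair the genotypes, too few of these splits part all pairs for a share under 0.05. For the sorted populations the real counts and the highest of the other splits were 13298 and 0 for cDC1 against B cells in WT and 13384 and 1 in March1-/-. For CD11cint against cDC1 they were 13534 and 2298. In each of these, 1 split, the real one, called as many. Chance can be excluded there only if the libraries are free of pairing, since the splits that part all 4 same-numbered pairs, 8 in each case, are too few for a share under 0.05. For CD11cint against March1-/- B cells, where the numbers pair the libraries, the real count was 4613, and the highest of the other splits that part all 4 pairs was 1, but these 8 splits are too few for a share under 0.05. Of all 35 splits the highest other called 329 and parted 2 of the pairs.

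Genotype calls clustered on chromosome 8, around March1 and from 30000001 to 40000000, and at the ends of chromosomes X and Y. At those ends the 5 genes tested on each fell in both cell types, and no explanation was tested. None was tested for the stretch from 30000001 to 40000000 either. An effect of March1 loss that does not depend on a gene's position is argued against by the odds ratio of 4.24 (3.09 to 5.72) in B cells. That interval takes genes as independent. Variants of another strain carried along with the targeted allele may account for the cluster around March1, and would be in every cell of the mouse. Direction was compared for genes called in either cell type, limited to those with a mean of at least 1 CPM in both. Of 62 such genes within 20 Mb of March1, 72.6% moved the same way in both cell types (Wilson interval 60.4 to 82.1). Of 895 such genes elsewhere it was 54.9%. The share near March1 lies between the 80% set for this explanation and the 60% set against it. Strain variants cannot be told apart from an effect of the loss, or of the altered allele, on its neighbours, which stays open as untested. The design holds no March1-/- mouse without the flanking stretch, and no sequence of these mice was analysed here.

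Transcripts of the other sorted population were higher in 2 groups of March1-/- libraries. B lineage cells or their RNA in the cDC1 libraries could account for the first. The genes taken here were called at least 4 log2 units higher in WT B cells than in WT cDC1. They also had a mean of at least 50 CPM in March1-/- B cells and in CD11cint cells. Of these 105 genes, 84.8% were higher in March1-/- than in WT cDC1 (76.7 to 90.4), with a median excess of 0.833% of the B cell level. Over all 105, with or without an excess, the excess was nearer the profile of CD11cint cells than of B cells (coefficient 1.51, bootstrap interval 1 to 2.32). A source like CD11cint cells gives 1 and one like March1-/- B cells 0. A value above 1 is reached by no mixture of these 2 sources. The interval was drawn over genes, so it does not measure the spread between libraries. For cDC1 RNA in the CD11cint libraries, the genes taken were called at least 6 log2 units higher in WT cDC1 than in WT B cells. They also had a mean of at least 50 CPM in March1-/- cDC1. Of these 109 genes, 89.9% were higher than in March1-/- B cells (82.8 to 94.3), with a median excess of 0.293% of the cDC1 level. Neither can be told apart from transcription of these genes by the sorted cells themselves, or from RNA taken up with membrane, since both shares lie between the 75% and 90% set for the tests and the purity of 95 to 99% allows either. Transcription of Itgax by CD11cint cells at an intermediate level is argued against by a log2 fold change over B cells of 0.0352 (−0.391 to 0.461), below a doubling.

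Marginal zone genes were lower and follicular genes higher in B cells labelled March1-/-. A candidate explanation is that cells of the CD11cint kind were sorted apart in March1-/- mice and stayed in the B cell sort of WT mice. Of 74 genes higher in CD11cint cells, 98.6% were lower in March1-/- B cell libraries 3 and 4 than in WT (92.7 to 99.8), and of 131 genes lower in CD11cint cells 88.5% were higher (82 to 92.9), where the genes had been chosen with libraries 1 and 2, a choice that a change of the B cells with genotype would favour as well. With genes chosen against WT B cell libraries 1 and 2 and tested with 3 and 4, a choice that favours genotype changes common to both March1-/- populations, the shares were 52.2% of 23 and 47.8% of 69 (33 to 70.8 and 36.5 to 59.4), so the explanations cannot be told apart without WT CD11cint cells. The germinal centre list argues against this as the whole cause, for the genes it covers. Of its 8 genes 5 fell and 0 rose in CD11cint cells, so its median would have to be above 0, but was −0.98. The fall in CD11cint cells was not called with an estimated correlation (camera adjusted p = 0.11). Its member Rgs13 moved in the direction of the explanation. A change of the B cells with genotype stays open as untested.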

How the results depend on the processing

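Some tests were chosen after the results were seen. They left out chromosome 8, the genes at least 16-fold higher in WT B cells than in WT cDC1, or all March1-/- libraries numbered 1. A window of all of chromosome 8 and sign flips within pairs were chosen then too, and the others were planned. No called result changed its direction under any alternative, and no gene called in both changed sign. Of 939 results for single genes, DESeq2 left 907 on the same side of the threshold (24 gained and 2 lost a call), limma-voom 916 (13 and 10), RLE factors 933 (2 and 4) and the compared groups alone 869 (20 and 35). Single-library omissions lost 299 and gained 66 such calls and left 8075 on the same side. In 109 cases a gene that was not called changed sign, and 21 had no value, because the gene was filtered out or had no adjusted p. Of 189 list results, limma-voom left 179 on the same side (8 gained, 2 lost), RLE factors 185 (4 lost) and single-library omissions 1640, with 41 gained and 47 lost.

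The count for CD11cint against March1-/- B cells was 4613, and 3018 in the fit of the compared groups alone, where 2926 of the genes were shared. For the interaction it was 441, 679 with DESeq2 (426 shared) and 680 with the replicate block (439 shared). Of 62 list calls 25 were made with an estimated correlation. The level of cDC1 genes in CD11cint cells was 2.53%, and its excess over B cells was no longer past 0.05 as a median of per-gene percentages (1.61%, exact permutation p = 0.171) or with RLE factors (2.507%, 0.0571). The cause was not tested for any of these, except that the median weighs each gene alike and not by its level.

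With each library left out in turn, the counts were 574 to 879 for genotype in B cells, 370 to 537 for genotype in cDC1, 3650 to 4751 and 13106 to 13713 for CD11cint against B cells and cDC1, 12891 to 13045 and 13006 to 13201 for cDC1 against B cells in WT and March1-/-, and 313 to 555 for the interaction. For genotype in B cells the count moved by over 1.5 times without March1-/- library 1 (590) or 3 (574) or WT library 1 (591) or 4 (592), with fewer libraries in the fit. List calls numbered 58 to 68. The position was 0.9743 to 0.9778, and not past 0.05 without CD11cint library 1 (exact permutation p = 0.0571). The level was 2.515% to 2.545%, with an exact permutation p of 0.0571 in each of the 4 omissions, while 3 against 4 libraries could reach 0.0286.

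The other settings stayed within 1.5 times for counts. For genotype in B cells and in cDC1, DESeq2 called 1227 and 664, limma-voom 957 and 558, RLE factors 919 and 535, no filter 815 and 525, the compared groups alone 907 and 622, lane L004 731 and 415, lane L005 715 and 396, the fit without immunoglobulin genes 864 and 518, and the fit without chromosome 8 767 and 455. For CD11cint against March1-/- B cells the count without immunoglobulin genes was 4495 of 18440 genes tested. Without all March1-/- libraries numbered 1, the counts were 893 and 495 for genotype in B cells and cDC1 (721 and 417 shared), 3802 and 13420 for CD11cint against B cells and cDC1, 13190 for cDC1 against B cells and 392 for the interaction. The position was 0.9619 to 0.9755 under the other thresholds, prior count and scaling, and 0.9878 without immunoglobulin genes, against 1.007 in March1-/- B cells, each with an exact permutation p of 0.0286. The odds ratio around March1 was 5.47 and 6.92 in B cells and cDC1 within 5 Mb, 4.17 and 4.56 with limma-voom, and 2.36 and 2.66 over all of chromosome 8. The overlap of genotype calls had odds ratios of 6.83 and 11.5 (higher and lower) with DESeq2, 2.85 and 2.87 at an unadjusted p, and 7.78 and 12.7 without chromosome 8, against 9.45 and 13.3.

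With the replicate number as a block, 1328 genes were called for genotype in B cells and 744 in cDC1. Same-numbered libraries of WT and March1-/- correlated at −0.0423 to 0.0506 in B cells (3 of 8 best with their own number), so no pairing was seen between these groups. In cDC1 they correlated at 0.0128 to 0.262 (7 of 8). Pairing is possible there, although not every correlation was above 0.1. Between B cells and cDC1 the correlation was 0.0893 to 0.315 in WT and 0.088 to 0.202 in March1-/- (8 of 8 each), and between cDC1 and CD11cint cells 0.0336 to 0.369 (7 of 8), a hint of shared origin from the data alone. With a block within genotype, 14346 genes were called for CD11cint against cDC1, 14113 and 14114 for cDC1 against B cells in WT and March1-/-, and 6128 for CD11cint against B cells, where the pairing holds. There the block gained 9 single-gene calls (Itgam, H2-K1, March5, Notch2, Pcna, Birc5, Ccnb1, Igha and Ighg3), lost 2 (Fcer1g and Cd209a), and changed no other call of a named gene. Over all comparisons fitted with this block, 3 list calls were gained and 1 was lost. For the position (0.9759) and level (2.53%), sign flips within the pairs of March1-/- B cell and CD11cint libraries gave an exact permutation p of 0.125. This is the smallest that 4 pairs allow, with all 4 pairs in 1 direction. Depth limits what can be seen at low levels: 3 counts correspond to 0.0916 to 0.1334 CPM, and genes changed 1.5-fold were called in 56% of cases in simulated March1-/- against WT B cells.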

Other observations

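The tests of shared pools of mice and of the immunoglobulin genes in this part were chosen after the results were seen, as were the genes named here.

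Of 266 immunoglobulin genes tested in CD11cint cells against March1-/- B cells, 117 fell, 148 did not pass edgeR's test and 1, Igkv2-107, rose (0.83 ± 0.18). Their median log2 fold change was −0.48. Camera called this set, which was not among the fixed lists, as lower (p = 3.91e-19, and p = 0.0189 with an estimated correlation). The 347 immunoglobulin genes made up 1.44% ± 0.108 of counts in CD11cint cells, 1.95% ± 0.0655 in March1-/- B cells and 2.01% ± 0.199 in WT B cells (n = 4 each). The share was lower in CD11cint cells in all 4 numbered pairs (exact permutation test, two-sided, p = 0.0286 over 70 assignments, and 0.125 by sign flips within pairs, the smallest that they allow). Of the genes that met the limits of the naming rule, 50 immunoglobulin genes were lower and 0 higher in CD11cint cells. Ighg1 was at 2.28 ± 0.652 against 20.2 ± 8.66 CPM (log2 fold change −3.14 ± 0.31, edgeR adjusted p = 3.61e-07) and Ighg2c at 5.98 ± 1.62 against 50.3 ± 60.7 CPM (−3.08 ± 0.70, edgeR adjusted p = 0.00401). The Ighg2c value rested on B cell library 3, at 140.7 CPM. Without it the B cell mean was 20.2 ± 9.23 CPM (n = 3) and the log2 fold change −1.77 (edgeR adjusted p = 0.0114). Ighg2b was at 26.1 ± 3.77 against 74.4 ± 27.9 CPM (−1.51 ± 0.24, edgeR adjusted p = 0.000124). Reads of these heavy chain genes can be shared between isotypes, so the split among them is uncertain. Igha and Ighg3 did not pass the test (edgeR adjusted p = 0.194 and 0.116) but did with the replicate block (0.0287 and 0.0188). Ighm, the heavy chain gene of IgM, was at 6489 ± 646 against 7578 ± 248 CPM (−0.22 ± 0.07, edgeR adjusted p = 0.0304), a call lost in 5 of the 8 fits that left out 1 library (0.0689 to 0.0915) and in the fit of the compared groups alone (0.146).

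In B cells labelled March1-/- against WT, Ighg2b was at 74.4 ± 27.9 against 165.3 ± 45.3 CPM and Ighg3 at 69.7 ± 11.5 against 120.1 ± 39.6 CPM (edgeR adjusted p = 0.00507 and 0.0111). Both calls were lost in the fit of the compared groups alone (0.115 and 0.136).

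Transcripts of chromosome Y and Xist, the RNA of the inactive X, were present together in all 20 libraries. Kdm5d was at 14.2 to 50.76 CPM, Eif2s3y at 18.1 to 56.63, Uty at 6.84 to 22.49, Ddx3y at 34.1 to 94.69 and Xist at 232 to 1082. None of these genes passed edgeR's test between the genotypes in B cells or cDC1, whereas 5 of the 11 tested genes of chromosome Y, all at its end, were lower in March1-/- in both. A candidate explanation is that libraries held cells of male and female mice, and that the libraries with the same number within a genotype came from the same pool. The library number within genotype explained 96% of the variance within groups of the mean log2 level of the 4 chromosome Y genes (exact permutation test, one-sided, p = 0.000506 over 13824 assignments, whose median was 40.5%). The labels do not say that mice were pooled.

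Mid1-ps1, the pseudogene copy of Mid1 on chromosome Y, fell together with Mid1 in libraries labelled March1-/-, by 2.69 in B cells and 1.69 in cDC1 on the log2 scale (edgeR adjusted p = 2.64e-07 and 7.42e-05). Neither gene lies on chromosome 8. All 5 genes tested from Mid1 to the end of chromosome X (169685199 to 170019281), which were Mid1, G530011O06Rik, Gm15726, Gm15247 and Gm21887, fell in both cell types, with log2 fold changes of −1.23 to −3.32 in B cells and −1.11 to −1.87 in cDC1. The 5 genes called on chromosome Y had −1.25 to −2.69 and −1.14 to −1.72. The cDC1 call of Gm21887 was lost in 4 of the 8 fits that left out 1 library (edgeR adjusted p = 0.0543 to 0.0989) and in the fit of the compared groups alone (0.137). Reads can be shared between the copies on X and Y and, without strand, between Mid1 and the 3 of these genes that overlap it, so the number of separate changes is uncertain. Several mitochondrial genes and their nuclear pseudogenes had nearly equal counts in every library. Gm10925 had 100.002 to 100.021% of the counts of mt-Atp6, Gm28437 100.003 to 100.018% of mt-Co3 and Gm28661 100.007 to 100.026% of mt-Co2, while Gm29216 had 35.191 to 44.074% of mt-Co1.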
